A study of Mus musculus with 30 samples.

How the data were processed

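Poly(A)-enriched RNA from mouse spleen and lymph node was measured by RNA sequencing in 30 libraries. Per the labels' protocols, RNA was isolated from frozen organs with a column kit, libraries were prepared with the NEBNext Ultra II RNA kit and sequenced on an Illumina instrument. The submitters' processing notes name bcl2fastq 1.17.1, TopHat2 2.1.0 and the mouse genome build mm10; the tool that turned alignments into gene values, its annotation and its filters are not given in the sources used here. The authors deposited RPKM values, that is read numbers scaled to the length of the transcript and to the mapped reads of the library, in 1 column per library, in 1 table for spleen and 1 for lymph node with 24957 gene symbols each. All sample columns were used. Groups were taken from the genotype, agent and tissue labels, and replicate numbers from the titles.

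RPKM is already divided by gene length and by library size, so the values were not treated as counts. The values include very small non-zero numbers, as estimated abundances do, and read numbers could not be recovered from them. Comparing low genes between libraries gave only a relative depth, from 1 to 2.26 in spleen and from 1 to 1.82 in lymph node; the absolute depth is unknown and no counting interval is given. RPKM is relative to the mapped reads of a library, so that the reads of a few very abundant transcripts, such as haemoglobin in spleen, lower the values of the other genes in that library. The sum of RPKM is not fixed, and ranged from 350314 to 506819 in spleen and from 368211 to 468564 in lymph node. None of the genes well expressed in most libraries of a tissue was listed at 0 in any of them (0 in each library). Their choice from the same values makes this likely beforehand. In all, 0 pairs of libraries held identical values.

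Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(RPKM + 0.5). Genes with an RPKM of at least 1 in at least 3 spleen or 4 lymph node libraries were kept, 11982 genes in spleen and 12285 in lymph node. All groups of a tissue entered 1 fit and shared the estimate of the spread, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. A gene past this threshold is said to have risen, fallen or passed. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. The spleen and lymph node tables were never tested against each other. The labels do not say that replicates came from separate animals, so that p-values measure only the spread between these samples, which may be technical.

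Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over the 32 lists tested in spleen or the 35 in lymph node. The same test with an estimated correlation is given beside it, since most list results did not pass there. In all 39 lists of pathway genes, of markers of blood, stromal and other tissue cells and of handling stress were fixed, with 635 genes, of which 626 are in the tables. Some genes are in several lists. Numbers of list members past the threshold are given over all genes and adjusted over the list alone. The genes named in the text were chosen by rule: Padi2 and Padi4, the 8 largest rises and 8 largest falls in the 5 main comparisons (3 and 3 in the others) among genes that passed, had no overlap between the libraries of both groups and had a mean of at least 2 RPKM in the higher group, and up to 4 members with the smallest p from each list that passed or had 3 members past the threshold. Unnamed clones, receptor segments and sex-linked genes were left out of the largest changes. With fewer than 5 genes named, the 5 smallest p-values were named. Some genes that this rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Sample groups, comparisons, tests, gene lists, the naming rule and most of the alternatives named below were fixed before the data were examined.

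Coordinates are from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, to which 24311 symbols matched directly and 24860 with synonyms. The model was tested on simulated data in which 200 genes were changed. For Pad2-/- against WT under imiquimod it recovered 48.5% of genes changed by 0.5 log2, 90.9% of those changed by 1 and 100% of those changed by 2 in spleen, where 6 of 165 calls were false. In lymph node it recovered 17.6%, 78.8% and 98.5%, with 7 of 136 calls false, so that changes of 0.5 log2 were mostly not detectable there. The simulated noise was independent between genes and had 1 spread per gene for all groups of a tissue. It held neither the larger spread of imiquimod spleens nor any structure among libraries. These rates therefore need not hold for the real libraries. Alternatives tried were pseudocounts of 0.1 and 1, no filter on low values, median-ratio scaling, quantile normalization, a fit of only the groups compared, the replicate number as a block, limma's array weights, a block of lymph node replicates 1 and 2 against 3 and 4 (whose library index numbers form separate runs in WT and Pad4-/-, while those of Pad2-/- replicates 3 and 4 follow directly on the first run), and leaving out each library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.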

Results

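The data are 30 mouse RNA-seq libraries, 18 of spleen and 12 of lymph node. The mice were wild type (WT, named FVB after an inbred strain in the titles) or lacked Padi2 (Pad2-/-) or Padi4 (Pad4-/-). These genes encode peptidylarginine deiminases, enzymes that convert arginine in proteins to citrulline. Spleens came from control mice and from mice given imiquimod, an agonist of Toll-like receptor 7 (TLR7), with 3 libraries for each genotype and agent. The extract protocol in the labels speaks only of imiquimod-treated mice, while the agent labels mark 9 spleen libraries as controls; the agent labels were followed, and every comparison of imiquimod with control rests on them. Lymph nodes came from imiquimod-treated mice alone, with 4 libraries per genotype. The series asks how the lymphoid organs of both knockouts respond to TLR7 activation relative to WT, as a model of lupus. Each library had 10905 to 12198 genes at 1 RPKM or more. The 10 most abundant genes held 7.22% to 23.9% of a spleen library's total RPKM, with the haemoglobin gene Hbb-b1 first in 4 imiquimod spleens, and 8.20% to 10.8% of a lymph node library's. The spread between libraries was larger under imiquimod: the median SD of log2(RPKM + 0.5) within a group was 0.0649 to 0.0766 in control spleens and 0.167 to 0.177 in imiquimod spleens. In lymph node it was 0.14 in WT, 0.25 in Pad2-/- and 0.216 in the libraries labelled Pad4-/-. Values below are mean RPKM ± SD over 3 spleen or 4 lymph node libraries per group, and log2 fold changes with ± give the standard error of the fit.

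The targeted genes lie in the cluster of peptidylarginine deiminase genes on chromosome 4 of GRCm38, with Padi3 and Padi1 between them, Padi4 at 140745508 to 140774239 and Padi2 at 140906336 to 140952586. Padi2 was at 9.77, 10.5 and 9.77 RPKM in the WT control spleens (SD 0.399), at a mean of 8.65 ± 0.102 in Pad4-/- and at 1.13 ± 0.0589 in Pad2-/-. Under imiquimod the spleen values were 5.04 ± 0.264 in WT, 5.93 ± 0.911 in Pad4-/- and 0.593 ± 0.110 in Pad2-/-. In lymph node Padi2 was at 5.45 ± 0.254 in WT, 0.748 ± 0.247 in Pad2-/- and 4.06 ± 0.702 in the libraries labelled Pad4-/-. Padi4 was at 1.57 ± 0.604 in WT control spleen, 3.39 ± 0.561 in Pad2-/- and 0.122 ± 0.0302 in Pad4-/-. In imiquimod spleen it was at 16.8 ± 8.59 in WT, 21.8 ± 4.68 in Pad2-/- and 0.149 ± 0.0980 in Pad4-/-.

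In the lymph node, Padi4 went against the label of 2 libraries. The WT libraries held 0.952, 0.869, 1.05 and 0.679 RPKM and the Pad2-/- libraries 8.16, 1.30, 7.91 and 4.85. The libraries labelled Pad4-/- held 0.0958 and 0.131 in replicates 1 and 2, as low as in Pad4-/- spleen. Replicates 3 and 4 held 0.607 and 1.2, just below and just above the WT range. Padi4 in the libraries labelled Pad4-/- therefore differed from WT by -0.60 ± 0.43 with a limma adjusted p of 1, which did not pass. Every direction given for Pad4-/- lymph node rests in part on replicates 3 and 4, so the group is called the libraries labelled Pad4-/- throughout.

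**Figure D1:**
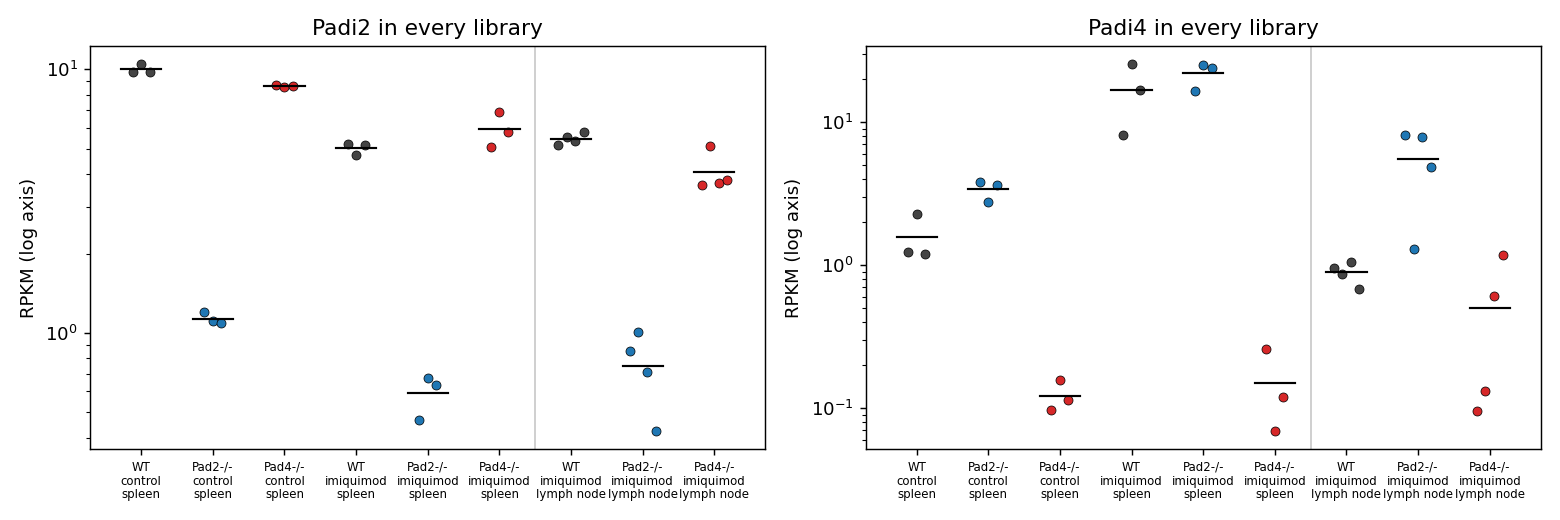
Padi2 and Padi4 in each of the 30 libraries, in RPKM on a log axis, by tissue, genotype and agent; points are libraries and short lines group means. Padi4 was at 0.607 and 1.2 RPKM in replicates 3 and 4 of the lymph node libraries labelled Pad4-/-, against 0.0958 and 0.131 in replicates 1 and 2.

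The response to TLR7 activation in WT spleen was given by imiquimod against control libraries. Genes of myeloid cells and of erythroid and granulocyte precursors rose, and B cell, pan-T cell and cytotoxic genes fell, while germinal centre B cell genes rose. As lists these passed only with the preset correlation, and 0 of 32 lists passed in camera with an estimated one (smallest adjusted p = 0.588). Fcgr4, an activating Fc receptor of monocytes and macrophages, rose by 6.03 ± 0.26, from 2.31 ± 0.432 to 184 ± 40.0 RPKM (n = 3 and 3, limma adjusted p = 5.81e-11). The other largest rises were Adamdec1 4.94, a metalloprotease of macrophages, Klf1 4.81, an erythroid transcription factor, Mt2 4.80, a metallothionein, Slpi 4.76, a secreted protease inhibitor, Prtn3 4.74, a granule protease, Cldn13 4.70 and Apol11b 4.63. The largest falls were those of Cr2, the complement receptor of B cells, at -3.77 ± 0.45 (11.8 ± 5.97 against 154 ± 3.12 RPKM), Ackr3 at -3.36, S1pr3, a receptor of marginal zone B cells, at -3.19, Cd209d at -3.09, the marginal zone gene Dtx1 at -3.01, Ell3 at -2.88 and Vipr1 at -2.58. Cd8a, the co-receptor chain of cytotoxic T cells, fell by 2.57 on the log2 scale (5.03 ± 1.27 against 31.8 ± 1.35 RPKM). Padi4 rose by 2.97 ± 0.30 and Padi2 fell by 0.92 ± 0.10.

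Genes of proliferation rose as a group in WT spleen. All 21 tested mitotic genes rose, with a median of 3.46 (Cdk1 3.75, Bub1b 3.63, Aurkb 3.31; list adjusted p = 1.34e-12), and so did all 23 DNA replication genes (median 2.28; Mcm10 3.35, Gins2 3.26, Cdc45 2.93; adjusted p = 2.43e-11). With an estimated correlation both lists had adjusted p = 0.588. All 15 neutrophil granule precursor genes rose (median 3.51; Elane 4.19, Ms4a3 3.94, Mpo 3.70; adjusted p = 0.000136), as did all 15 mature neutrophil genes (median 2.52; S100a8 3.70, S100a9 3.46, Clec4e 2.52; adjusted p = 0.00144). Of 18 monocyte and macrophage genes 17 rose (Ms4a6d 3.84, Cd68 2.07, Sirpa 2.06; adjusted p = 1.01e-05), and of 13 resident macrophage genes 11 rose and 1 fell (Itgad 3.75, Cd5l 3.42, Adgre1 2.16; adjusted p = 0.00108). All 27 erythroid genes rose (median 3.42; Car1 4.19, Gata1 3.81, Nfe2 3.18; adjusted p = 0.000543) and 16 of 17 megakaryocyte genes (Pf4 3.92, Gp9 3.70, Ppbp 3.67; adjusted p = 0.00188). Complement genes rose in 11 of 12 and fell in 1 (C1qb 3.63, C1qc 3.53, C1qa 3.45; adjusted p = 0.00463), and 19 of 20 genes of the unfolded protein response and secretion rose (Derl3 2.82, Sdf2l1 2.03, Manf 1.49; adjusted p = 8.45e-06). For each of these lists the adjusted p with an estimated correlation was between 0.588 and 0.654. Adjusted over the list alone, the numbers of genes were the same except that all 20 secretory genes rose.

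Of 32 type I interferon-stimulated genes 24 rose and 2 fell (median 1.07; Oas1a 2.40, Cmpk2 1.81, Ifih1 1.42 and Ddx58 -1.01; list adjusted p = 0.0287, and 0.692 with an estimated correlation). Inflammatory cytokines and chemokines rose in 12 of 17 and fell in 3 (Tnfsf13b 2.09, Il10 2.03, Il27 1.92; adjusted p = 0.0497, and 0.588 with an estimated correlation), and 14 rose when adjusted over the list alone. Germinal centre B cell genes rose in 9 of 12 (Mef2b 2.57, Nuggc 2.55, S1pr2 2.08; adjusted p = 0.049) and progenitor genes in 8 of 12 (Gfi1b 3.57, Myb 1.80; adjusted p = 0.0413), with adjusted p = 0.692 and 0.588 with an estimated correlation. Among the other lymphocyte lists that passed, 17 of 18 B cell genes fell (median -1.48; Cr2 -3.77, Ralgps2 -2.04, Fcer2a -1.96; adjusted p = 8.45e-06), as did 19 of 20 pan-T cell genes (median -0.996; Cd8a -2.57, Cd8b1 -2.35, Lef1 -2.17; adjusted p = 1.49e-06) and 13 of 17 natural killer and cytotoxic genes, of which 2 rose (median -1.40; Ncr1 -2.39, Klrd1 -2.19, Ctsw -1.88; adjusted p = 0.000136). With an estimated correlation these p-values were 0.588. Adjusted over the list alone, the numbers of these genes were the same. Other lists did not pass: interferon-gamma response (13 rose and 1 fell of 21, or 10 and 1 adjusted over the list alone, Iigp1 2.82, Cxcl10 2.12; adjusted p = 0.113), plasma cell (9 and 3 of 14, Jchain 3.81; adjusted p = 0.108), TLR and NF-kB signalling (5 and 10 of 22, Tlr8 2.83, Tlr3 -0.90; adjusted p = 0.241), inflammasome and lysosomal protease (8 and 4 of 15, Ctsb 1.77; adjusted p = 0.241), plasmacytoid dendritic cell (5 and 9 of 14; adjusted p = 0.146), conventional dendritic cell (5 and 5 of 16; adjusted p = 0.556) and marginal zone B cell genes (5 and 8 of 14; adjusted p = 0.182). The eosinophil (7 and 1 of 9, adjusted p = 0.0881), mast cell (6 and 1 of 9, adjusted p = 0.196), regulatory T (5 and 1 of 10, adjusted p = 0.241), Th1 (2 and 4 of 12, adjusted p = 0.487), Th2 (4 and 2 of 6, adjusted p = 0.491), follicular helper T (6 and 2 of 11, Pdcd1 3.50, Il21 1.86; adjusted p = 0.423), adipocyte (3 and 1 of 5, adjusted p = 0.281) and handling stress lists (6 and 2 of 13, adjusted p = 0.241) did not pass either. For these other lists the numbers adjusted over the list alone were the same. Th17, stromal, gland, pancreatic, keratinocyte, skeletal muscle and peptidylarginine deiminase genes had fewer than 5 tested members in spleen.

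**Figure D2:**
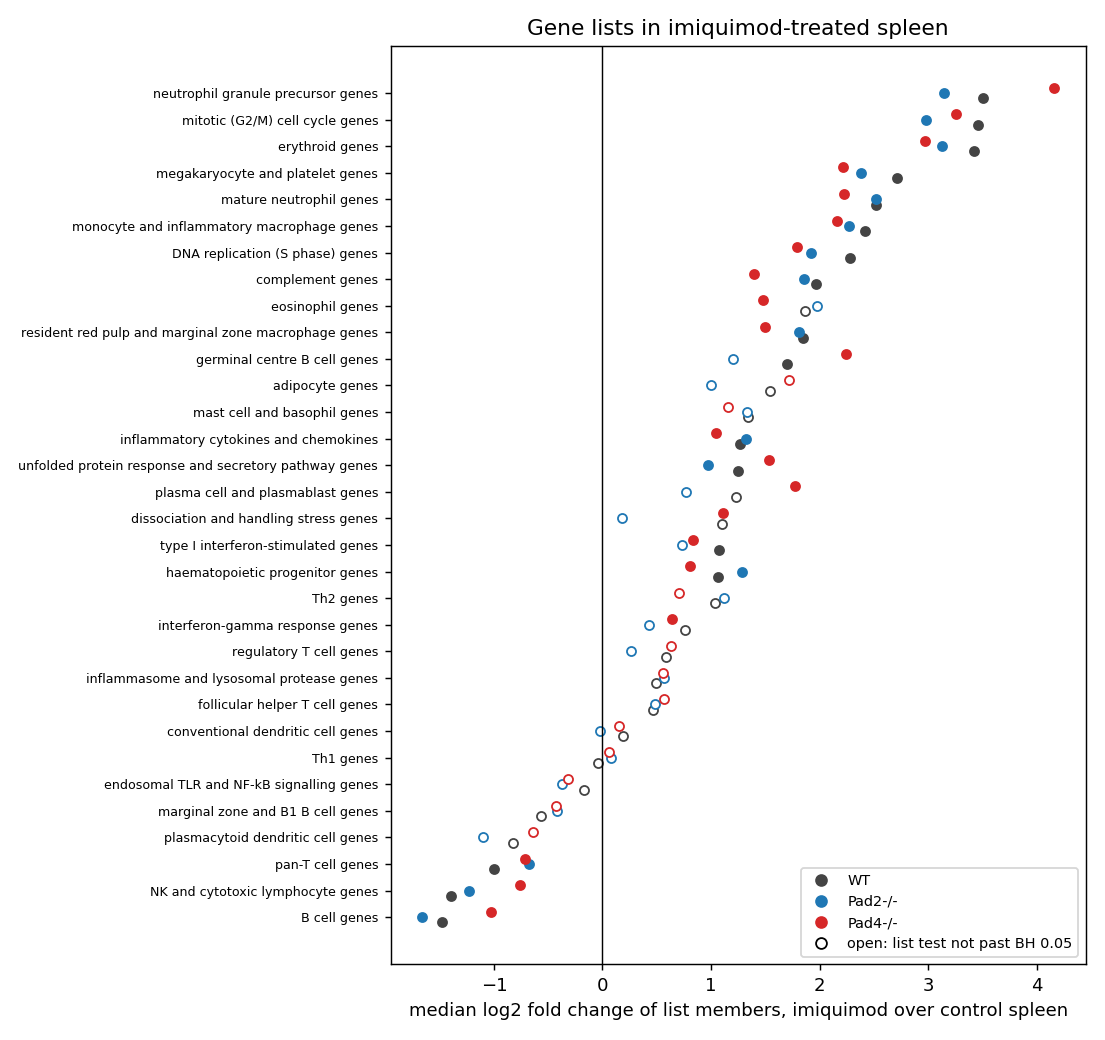
Median log2 fold change of the members of each gene list, imiquimod over control spleen, for WT, Pad2-/- and Pad4-/-; each point is a list in a genotype, open where the list test did not pass. Mitotic genes were at a median of 3.46 in WT, 2.98 in Pad2-/- and 3.26 in Pad4-/-, and B cell genes at -1.48, -1.66 and -1.03.

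In all, 4823 genes rose and 3984 fell in WT spleen, 2003 and 891 of them by more than 2-fold in limma's fit, and 9020 of 11982 had an unadjusted p under 0.05. With quantile normalization the split was 3868 higher and 5390 lower, and the median of all genes shifted by -0.195 log2, so that the direction of small changes depends on the scaling. No list median changed sign under quantile normalization or median-ratio scaling among lists that passed here. Haemoglobin differed widely among the imiquimod spleens, with Hbb-b1 at 2281, 3296 and 8672 RPKM in WT.

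The same comparison was made within each knockout, with 3 libraries per group. Fcgr4 rose by 6.0 ± 0.26 in Pad2-/- (164 ± 9.73 against 2.20 ± 0.929 RPKM) and 6.42 ± 0.26 in Pad4-/- (182 ± 50.4 against 1.63 ± 0.488), Apol11b by 5.12 and 4.89, and Adamdec1 by 4.82 and 4.80. Cr2 fell in both, at -4.00 and -3.32, as did S1pr3 at -3.17 and -2.97. Dtx1 in Pad2-/- (-3.05) and Retnla, a product of alternatively activated macrophages, in Pad4-/- (-3.44) were also among the 3 largest falls. Padi4 rose by 2.51 ± 0.30 in Pad2-/- and was at 0.05 ± 0.30 in Pad4-/- (limma adjusted p = 0.885). The 21 mitotic and 23 DNA replication genes all rose in both knockouts, the former with medians of 2.98 and 3.26 (adjusted p = 8.72e-14 and 6.93e-16), and so did the 15 genes of each neutrophil list. No list passed with an estimated correlation in either knockout (0 lists with camera), and the adjusted p was then 0.491 to 0.613 in Pad2-/- and 0.516 to 0.604 in Pad4-/- for the lists that passed with the preset one. Of B cell genes 17 of 18 fell in each knockout (medians -1.66 and -1.03), and of pan-T cell genes 17 of 20 (Lef1 -1.95 in Pad2-/-, Lef1 -1.61 in Pad4-/-). Erythroid genes rose in 27 of 27 in Pad2-/- (median 3.13, adjusted p = 0.000106) and 20 of 27 in Pad4-/- (median 2.97, adjusted p = 0.000222). In Pad4-/- the germinal centre and plasma cell lists (Fkbp11 3.47, Derl3 3.16) passed with adjusted p = 0.00207 each and the interferon-gamma response list with adjusted p = 0.0227, and with adjusted p = 0.528, 0.528 and 0.594 with an estimated correlation. Whether these responses differ from WT is tested below by the interaction.

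In Pad2-/-, 4348 genes rose and 4395 fell, with 12 lists higher and 3 lower; in Pad4-/-, 4062 rose and 4325 fell, with 18 lists higher and 3 lower. With quantile normalization the splits were 3741 higher and 5368 lower in Pad2-/- and 3493 and 5223 in Pad4-/-, so that the balance of rises and falls depends on the scaling here too. The median of all genes shifted by -0.111 log2 with quantile normalization in Pad2-/-.

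To ask whether the loss of Padi2 alone altered spleen, Pad2-/- control libraries were compared with WT control libraries. Zfp534, a KRAB zinc finger gene, was higher by 4.15 ± 0.17 (8.68 ± 0.588 against 0.0161 ± 0.0149 RPKM, n = 3 and 3, limma adjusted p = 9.89e-10), Zfp990 by 3.07 ± 0.15 and Cort, which encodes the neuropeptide cortistatin, by 2.06 ± 0.17. Padi2 fell by 2.69 ± 0.10, Miip fell by 0.44 ± 0.08 and Ahsa1, a co-chaperone of HSP90, fell by 0.37 ± 0.06. Zfp534 and Zfp990 are in a cluster of near-identical zinc finger genes, so that their reads, and their values, are uncertain. Of the 17 genes that passed (13 higher, 4 lower), 14, Padi2 itself included, lay within 10 Mb of Padi2, among 204 tested there, against 3 of 11744 elsewhere (Fisher's exact test, two-sided, p = 7.43e-23). The 3 others, named after their values were seen, were Ahsa1, Atp9a (1.06) and D17H6S56E-5 (0.91). Mitotic genes were higher as a list, each of the 21 by direction with a median of 0.39 (adjusted p = 4.19e-31), as were erythroid (median 1.13, adjusted p = 2.84e-09), neutrophil precursor (median 0.72, adjusted p = 7.73e-09), mature neutrophil, eosinophil and DNA replication genes, while the secretory and cytotoxic lists were lower. No member of these lists passed over all genes (0 with limma, where 235 of all genes had an unadjusted p under 0.05), 16 mitotic genes passed when adjusted over the list alone, and the smallest adjusted p with an estimated correlation was 0.201. Under quantile normalization 12 genes were higher and 8 lower. The fit of all spleen groups shares a spread that includes the more variable imiquimod libraries: a fit of only the 2 control groups gave 27 higher and 16 lower, of which, Padi2 left out, 16 lay within 10 Mb of Padi2 and 26 elsewhere (Fisher's exact test, two-sided, p = 3.01e-18), and array weights gave 63 higher and 36 lower. Of the 6 genes named by rule, Miip and Ahsa1 did not pass when some single libraries were left out. Dhrs3, Cenps and the other genes near Padi2 are given with their positions in the map of chromosome 4. The count fell to 11 without WT control replicate 1 or 3 and to 10 without Pad2-/- control replicate 3.

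In Pad4-/- against WT control spleen, 6 genes were higher and 12 lower, but this count and its balance depend on the fit: with only the 2 control groups in it, 919 genes were higher and 405 lower, and with array weights 1352 and 406. Snora16a (2.74 ± 0.43) and Snora44 (2.40 ± 0.35) were highest, both small nucleolar RNAs that a poly(A) library counts poorly and that lie within a host gene, and Hyi was higher by 0.98 ± 0.14 (23.8 ± 1.01 against 11.8 ± 0.898 RPKM). Alpl, the tissue-nonspecific alkaline phosphatase, fell by 1.62 ± 0.26 (0.570 ± 0.131 against 2.78 ± 0.377), Zbtb8a fell by 1.04 ± 0.10, Cxcr4, a chemokine receptor that retains cells in bone marrow, fell by 0.92 ± 0.13 and Padi4 fell by 1.69 ± 0.30. Of the 18 genes, 7, Padi4 itself included, lay within 10 Mb of Padi4, among 203 tested there, against 11 of 11745 elsewhere (Fisher's exact test, two-sided, p = 1e-08), and 12 lay on chromosome 4, from 118359999 on. With only the 2 control groups in the fit, and Padi4 left out, 43 lay near the locus against 1277 elsewhere (Fisher's exact test, two-sided, p = 2.06e-05). Hsp90aa1 (-0.80), Hspa8 (-0.62), Cacybp (-0.49) and Ahsa1 (-0.46), genes of the HSP90 and HSP70 chaperones chosen after their values were seen, were among those that fell. Pan-T cell genes were higher as a list, all 20 by direction (median 0.22, adjusted p = 0.00038), and 13 lists were lower, led by natural killer and cytotoxic genes (median -0.32, adjusted p = 4.78e-11), neutrophil precursor genes (median -0.89, adjusted p = 6.17e-11), handling stress genes (median -0.26, adjusted p = 4.75e-06) and Th1 genes (adjusted p = 2.14e-05). No member passed over all genes (0 with limma, 801 of all genes at an unadjusted p under 0.05), 3 cytotoxic genes did when adjusted over the list alone, and with an estimated correlation the smallest list p was 0.0736. The count was 7 without WT control replicate 3 or Pad4-/- control replicate 3, 8 without Pad4-/- control replicate 2, 9 without WT control replicate 1 or Pad4-/- control replicate 1 and 11 without WT control replicate 2. Of the 7 genes named by rule, Hyi and Zbtb8a passed whichever library was left out, and Alpl and Padi4 passed in 0 of the 6 such fits.

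**Figure D3:**
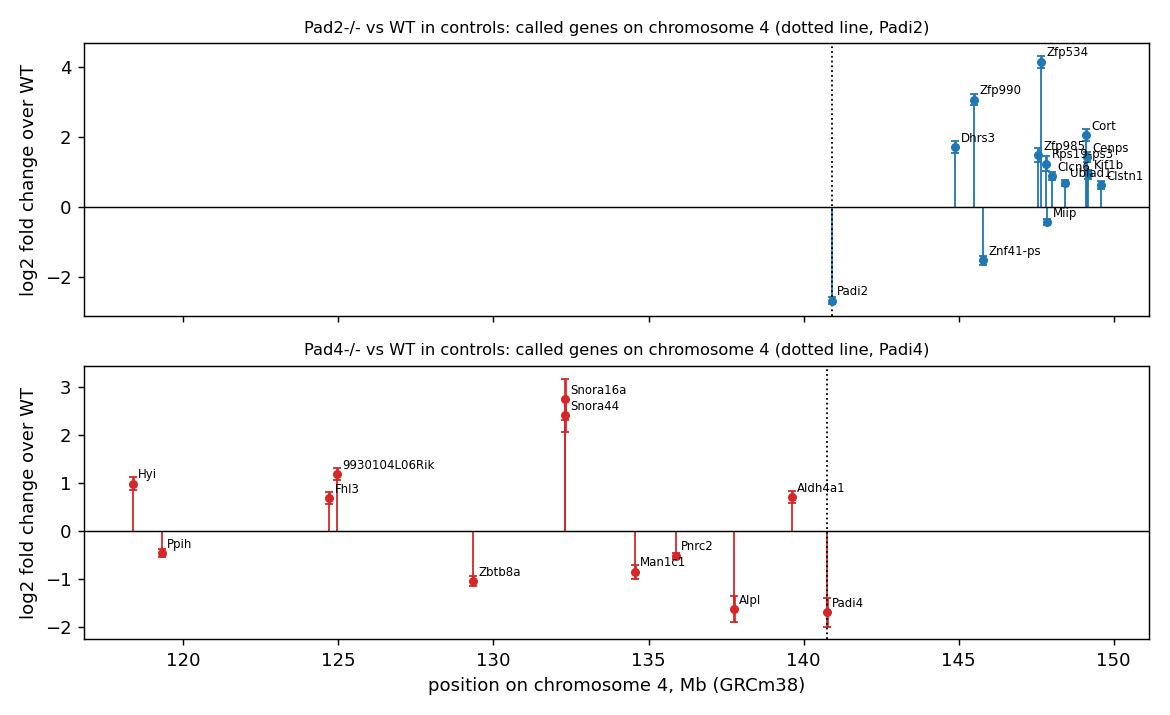
Log2 fold change over WT control spleen of the genes called on chromosome 4, by position in Mb, for Pad2-/- and Pad4-/-; each point is a gene with its standard error and the dotted line marks the targeted gene. The 13 other genes called within 10 Mb of Padi2 start between 144892534 and 149585111, and the 6 near Padi4 between 132309465 and 139622871.

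How the loss of Padi2 altered the TLR7 response was first asked of imiquimod spleens. Angptl7, a secreted angiopoietin-like protein, was higher than in WT by 2.55 ± 0.13 (4.38 ± 0.212 against 0.333 ± 0.0482 RPKM, n = 3 and 3, limma adjusted p = 1.41e-08), Zfp534 by 2.30 and Cd8a by 0.99 ± 0.14 (10.3 ± 0.744 against 5.03 ± 1.27 RPKM, adjusted p = 0.00324). Gpcpd1 (0.96), Dhrs3 (0.81), Ctsw, a cathepsin of cytotoxic lymphocytes (0.66), Tcp11l2 (0.60), Ypel3 (0.58) and the natural killer receptor Klrd1 (0.53) were also higher. Padi2 fell by 2.35 ± 0.10, and Zfp982 (-1.14), Zfp992 (-0.73), Cenpv (-0.70), Ccdc117 (-0.59), the chaperone Hspa8 (-0.58), Ppa1 (-0.57) and Psat1 (-0.51) were lower. Padi4 was at 0.48 ± 0.30 (adjusted p = 0.478). Angptl7 starts at 148495181 on chromosome 4 and Dhrs3, Zfp534, Zfp982 and Zfp992 also lie within 10 Mb of Padi2, where 13 of 204 tested genes passed against 45 of 11744 elsewhere (Fisher's exact test, two-sided, p = 1.15e-11). With Padi2 itself left out, 12 of 203 did (Fisher's exact p = 1.51e-10).

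Among gene lists, 8 were higher and 3 lower in Pad2-/- imiquimod spleen. Pan-T cell genes were higher by direction in 19 of 20 (median 0.26, adjusted p = 5.24e-10), with Cd8a past the threshold and 5 genes adjusted over the list alone, and natural killer and cytotoxic genes in 14 of 17, with 2 called, also over the list alone (adjusted p = 7.86e-07). Erythroid (median 0.78, adjusted p = 1.16e-05), mature neutrophil (0.51, adjusted p = 0.000134), neutrophil precursor (0.54, adjusted p = 0.00229), Th1, cytokine and progenitor lists were also higher. All 20 secretory and unfolded protein response genes were lower by direction (median -0.38, adjusted p = 7.86e-07), as were DNA replication and plasma cell genes; 0 secretory genes passed over all genes with limma and 12 adjusted over the list alone. Each list had an adjusted p of 0.667 with an estimated correlation. In all, 18 genes were higher and 40 lower, with 1872 of 11982 at an unadjusted p under 0.05, but the split was 19 higher and 11 lower with median-ratio scaling and 23 and 16 with quantile normalization. Single libraries set the count: it was 12 without WT imiquimod replicate 1 or Pad2-/- imiquimod replicate 3, 24 without WT replicate 3, 99 without Pad2-/- replicate 1, 628 without WT replicate 2 and 739 without Pad2-/- replicate 2, while a fit of only the 2 groups gave 2 genes and the replicate number as a block 32. The spread shared by all spleen groups includes the less variable controls and so is on the whole too small for imiquimod spleens. Of the 17 genes named by rule that passed, 6 (Angptl7, Cd8a, Ctsw, Padi2, Zfp534 and Zfp982) passed whichever library was left out.

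In Pad4-/- imiquimod spleen both genes of the CD8 co-receptor were higher than in WT. Cd8b1 was higher by 2.06 ± 0.21 (43.3 ± 7.30 against 10.5 ± 3.84 RPKM, n = 3 and 3, limma adjusted p = 0.000152) and Cd8a by 1.83 ± 0.14 (18.8 ± 0.498 against 5.03 ± 1.27, adjusted p = 3.99e-06). Dapl1 (1.59), Id3, an inhibitor of E proteins in lymphocytes (1.2), the granzyme gene Gzmm (1.13), Fcer2a, the low-affinity IgE receptor of B cells (1.0), Ctsw (0.97) and Klrd1 (0.88) were also higher, and Snora44 was at 1.99. Padi4 fell by 4.61 ± 0.30. Rap1gap (-2.19), Podxl (-1.95), C2cd4a (-1.85), the fatty acid carrier Fabp5 (-1.56), Mt2 (-1.49) and Pklr, pyruvate kinase of liver and red cells (-1.41), were lower, as was Rn4.5s (-2.20), a short repeat-derived RNA whose reads are uncertain. Padi2 was at 0.21 ± 0.10 (adjusted p = 0.216). Id3, Rap1gap and Snora44 lie within 10 Mb of Padi4, where 31 of 203 tested genes passed against 839 of 11745 elsewhere (Fisher's exact test, two-sided, p = 9.25e-05). With Padi4 itself left out, 30 of 202 did (Fisher's exact p = 0.000169).

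Pan-T cell genes were higher by direction in 19 of 20 (median 0.43, adjusted p = 3.27e-13), with 7 past the threshold over all genes (Cd8b1 2.06, Cd8a 1.83, Ccr7 0.90, Lat 0.63) and 12 adjusted over the list alone; the adjusted p was 0.608 with an estimated correlation. Natural killer and cytotoxic genes had 3 of 17 higher (Ctsw 0.97, Klrd1 0.88, Prf1 0.53; 5 adjusted over the list alone; adjusted p = 4.71e-06, and 0.608 with an estimated correlation), and B cell genes 3 of 18 (Fcer2a 1.0, Fcmr 0.73, Cd79b 0.71; 3 adjusted over the list alone; adjusted p = 6.45e-06, and 0.809). Plasma cell (median 0.42, adjusted p = 1.01e-05), germinal centre (0.48, adjusted p = 0.000965) and marginal zone B cell lists (0.28, adjusted p = 0.0214) were higher with 0 members called by limma (adjusted p = 0.738, 0.809 and 0.738 with an estimated correlation). Of 23 DNA replication genes 13 fell (Chaf1b -0.74, Rrm1 -0.59, Gins2 -0.57, Mcm5 -0.53; median -0.45, adjusted p = 3.82e-10, and 0.738 with an estimated correlation) and 22 when adjusted over the list alone, while 1 of 21 mitotic genes fell (Cdc20 -0.47; adjusted p = 0.000965, and 0.839). Megakaryocyte genes were lower by direction in all 17 (median -0.93, adjusted p = 0.00176, and 0.839 with an estimated correlation), with 0 called, and 3 handling stress genes fell (Dusp1 -0.76, Dnajb1 -0.64, Hsph1 -0.61) in a list that did not pass. In all, 189 genes were higher and 682 lower (2848 at an unadjusted p under 0.05). The split was 470 and 614 with median-ratio scaling and 429 and 415 with quantile normalization. Without Pad4-/- imiquimod replicate 1 it was 341 and 307, so that the balance rests in part on this library. The count was 139 without WT imiquimod replicate 3, 336 without Pad4-/- imiquimod replicate 3, 578 without Pad4-/- replicate 2 and 1507 without WT replicate 2, while a fit of only the 2 groups gave 4 genes. Here too the spread shared with the control spleens is on the whole too small. Of the 30 genes named by rule that passed, 14 passed whichever library was left out, among them Cd8a, Cd8b1, Ctsw, Dapl1, Gzmm, Id3, Klrd1, Fabp5 and Rap1gap.

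**Figure D4:**
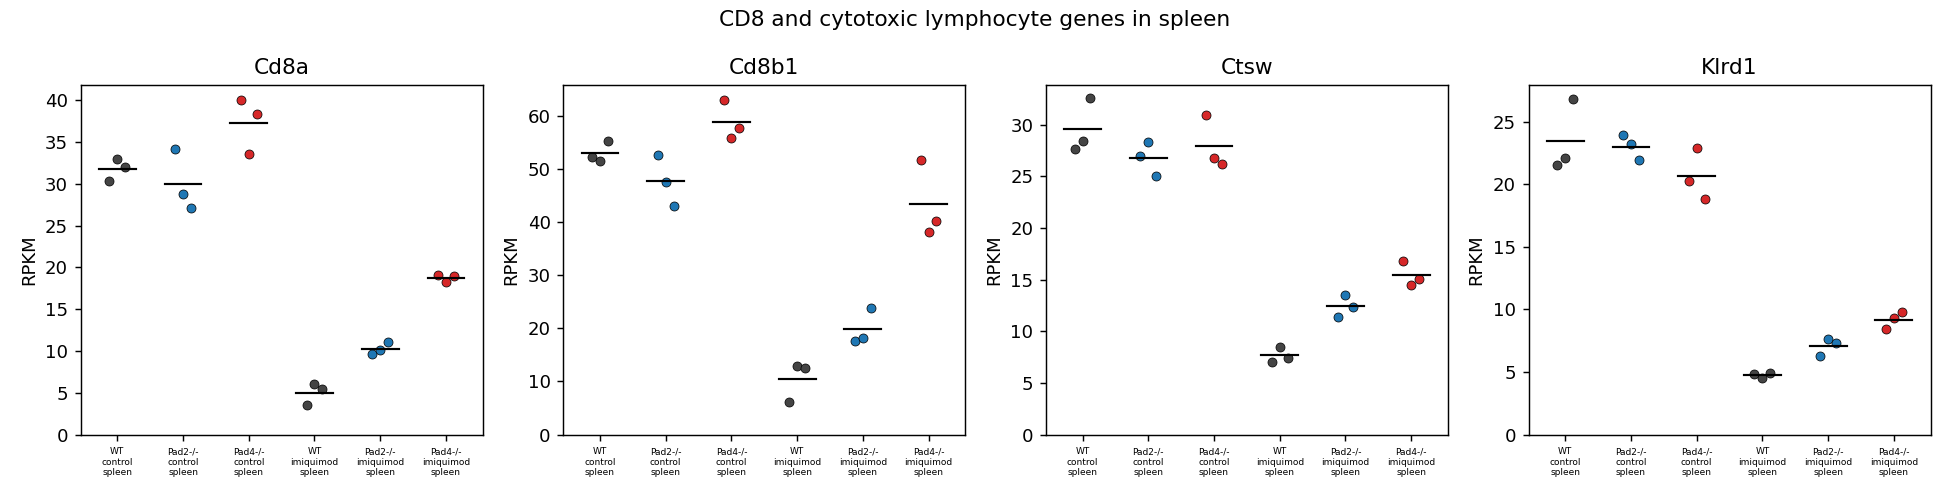
CD8 and cytotoxic lymphocyte genes in the 18 spleen libraries, in RPKM, by genotype and agent; points are libraries and short lines group means. Cd8a was at 5.03 ± 1.27 RPKM in WT, 10.3 ± 0.744 in Pad2-/- and 18.8 ± 0.498 in Pad4-/- imiquimod spleen.

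Whether the response to imiquimod itself differed from WT was tested as an interaction. Cd8a fell by 2.57 in WT and fell by 0.97 in Pad4-/-, and Cd8b1 fell by 2.35 in WT and was at -0.45 in Pad4-/-, where it did not pass. The response of Cd8b1 was higher in Pad4-/- than in WT by 1.91 ± 0.30 (limma adjusted p = 0.0169, n = 3 per group), as was that of Cd8a (1.60 ± 0.19, adjusted p = 0.00347), Gzmm (1.42 ± 0.17, adjusted p = 0.00347), Klrd1 (1.06 ± 0.14, adjusted p = 0.00364) and Ctsw (1.05 ± 0.14, adjusted p = 0.00364). Samd3, the sixth gene with a higher response, differed by 0.91 (adjusted p = 0.0485; named after its value was seen). Padi4 (-2.91 ± 0.42) and Rn4.5s (-2.70 ± 0.40) had the lower response. Natural killer and cytotoxic genes had a higher response as a list, all 17 by direction with a median of 0.74, 2 called over all genes and 9 adjusted over the list alone (adjusted p = 3.29e-17), and this list passed with an estimated correlation as well (adjusted p = 0.0472). The mean log2(RPKM + 0.5) of these genes was 3.16 in WT and 2.84 in Pad4-/- controls and 2.1 and 2.43 under imiquimod, so that lower control values in Pad4-/- form part of the difference in response. Of 32 lists 12 had a higher response, pan-T, B, plasma and secretory genes among them, and DNA replication genes a lower one (median -0.47, adjusted p = 3.41e-06, and 0.583 with an estimated correlation). The germinal centre list had a median of 0.32 (adjusted p = 0.00922, and 0.743 with an estimated correlation) and the plasma cell list one of 0.45 (adjusted p = 3e-06, and 0.423), while the interferon-gamma response list did not pass. Of the other lists the smallest adjusted p with an estimated correlation was 0.163. The count of 8 genes (6 higher, 2 lower; 1729 at an unadjusted p under 0.05) was 4 without WT control replicate 1 or 3, 756 without WT imiquimod replicate 2 (40 higher, 716 lower) and 665 with array weights (108 higher, 557 lower). Cd8a, Ctsw, Gzmm and Klrd1 passed whichever library was left out, and Cd8b1, Padi4 and Rn4.5s did not.

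For Pad2-/- the interaction gave 4 genes (936 at an unadjusted p under 0.05). Angptl7 rose by 1.96 in Pad2-/- and was at 0.05 in WT, a difference of 1.91 ± 0.18 (limma adjusted p = 0.000246, n = 3 per group), and the response of Zfp534 (-1.85 ± 0.25), Zfp990 (-1.61 ± 0.21) and Cenps (-1.34 ± 0.20) was lower. All 4 lie on chromosome 4 within 10 Mb of Padi2. Pan-T (median 0.25, adjusted p = 1.62e-10) and cytotoxic genes (0.33, adjusted p = 3.31e-10), Th1 and progenitor genes had a higher response as lists, and mitotic (-0.48, adjusted p = 2.26e-08), DNA replication, secretory and plasma cell genes a lower one, with 0 members called over all genes in limma, and 2 pan-T, 2 cytotoxic and 8 mitotic genes adjusted over the list alone. The smallest list p with an estimated correlation was 0.29. Without WT imiquimod replicate 2 the count was 7, and Cenps did not pass in 8 of the 12 fits that each left out 1 library.

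The knockouts were compared directly in imiquimod spleen. Padi4 was higher in Pad2-/- than in Pad4-/- by 5.09 ± 0.30 and Padi2 lower at -2.55 ± 0.10. Angptl7 (2.72) and Zfp534 (2.23) were higher and Dapl1 (-1.14), Gzmm (-1.11), Cd8b1 (-1.10), Fcer2a (-1.01) and Cd8a (-0.84 ± 0.14, limma adjusted p = 0.00988, n = 3 and 3) lower. All 14 plasma cell genes were lower in Pad2-/- by direction (median -0.86, adjusted p = 1.01e-11), 13 of them adjusted over the list alone, as were 19 of 20 secretory genes (median -0.42, adjusted p = 1.01e-11; 16 over the list alone) and all 18 B cell genes (median -0.64, adjusted p = 6.41e-09; 10 over the list alone). Germinal centre and pan-T lists were lower too, and 10 lists were higher, erythroid (median 1.08, adjusted p = 2.03e-06), both neutrophil and both cell cycle lists among them. With an estimated correlation the lists had adjusted p = 0.573 to 0.618. In all 16 genes were higher and 24 lower, and with quantile normalization 23 and 59. The count was 18 without Pad4-/- replicate 3, 20 without Pad2-/- replicate 1, 22 without Pad2-/- replicate 3, 98 without Pad4-/- replicate 1 and 1751 without Pad2-/- replicate 2, and a fit of only the 2 groups gave 3. As above, the spread shared with the control spleens is on the whole too small here. Of the 9 genes named by rule, Cd8a, Cd8b1, Dapl1 and Fcer2a did not pass when some single libraries were left out.

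In the lymph node of imiquimod-treated Pad2-/- mice, neutrophil genes were higher than in WT. Retnlg, a resistin-like protein of neutrophils, was higher by 3.88 ± 0.59 (423 ± 244 against 24.8 ± 15.3 RPKM, n = 4 and 4, limma adjusted p = 0.0133). S100a8 (3.48) and S100a9 (3.40), the subunits of calprotectin, the collagenase Mmp8 (3.47), Wfdc21 (3.40), Camp, the cathelicidin (3.33), Ifitm6 (3.10) and Lcn2, lipocalin 2 (2.97), followed. S100a8 was at 1725 ± 993 against 139 ± 87.7 RPKM. Of 13 mature neutrophil genes 10 were higher (Mmp9 2.85, Clec4e 1.54; median 1.83, adjusted p = 1.07e-36) and all 13 when adjusted over the list alone; of 14 precursor genes 8 were higher (Cd177 2.89, Cebpe 1.93; median 2.89, adjusted p = 3.74e-36) and all 14 over the list alone. These lists passed with an estimated correlation (adjusted p = 0.0258 and 0.0422), as did eosinophil genes (median 0.66; 0 of 6 over all genes and 4 over the list alone; adjusted p = 6.42e-05, and 0.0258 with an estimated correlation). Padi4 was at 1.90 ± 0.43 (adjusted p = 0.0891).

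Interferon-response genes were lower as lists in Pad2-/- lymph node. Oasl1 (-1.15) fell, 29 of 32 type I interferon-stimulated genes were lower by direction (median -0.43, adjusted p = 1.06e-07) with 7 past the threshold over the list alone, and 21 of 22 interferon-gamma response genes (median -0.63, adjusted p = 4.33e-10) with 15 over the list alone. Both lists had adjusted p = 0.599 with an estimated correlation. B cell genes were lower (median -0.56, adjusted p = 7.84e-06; 7 over the list alone; adjusted p = 0.789 with an estimated correlation), as were conventional dendritic cell, TLR signalling and both cell cycle lists, with adjusted p between 0.0151 and 0.0236. Secretory, plasma cell and mast cell lists were higher (adjusted p = 0.00055, 0.0236 and 0.0183), the last with Hdc (1.66), which neutrophils also express, as its called member. With an estimated correlation the adjusted p of these other lists was 0.599 to 0.923. Several of these lists moved with Pad2-/- replicates 3 and 4, which stand apart in other genes. Their mean log2(RPKM + 0.5) of B cell genes was 4.92 and 4.4, against 5.47 and 5.7 in Pad2-/- replicates 1 and 2 and 5.53 to 5.95 in WT. That of conventional dendritic cell genes was 2.84 and 2.42, against 3.47 and 3.84 in replicates 1 and 2 and 3.28 to 3.9 in WT. Without replicates 3 and 4 the secretory and plasma cell lists turned lower (medians -0.31 and -0.26, adjusted p = 1.77e-08 and 4.4e-06). The conventional dendritic cell, TLR signalling and eosinophil lists then did not pass (adjusted p = 0.436, 0.0957 and 0.0762). B cell genes had a median of -0.06 (adjusted p = 0.00332). Both interferon lists stayed lower without them (medians -0.17 and -0.35, adjusted p = 3.94e-09 and 4.55e-09), as did both cell cycle lists. The mature neutrophil (median 1.36), neutrophil precursor (median 1.72, adjusted p = 1.88e-15 for both) and mast cell lists stayed higher. In that fit 0 lists passed in camera with an estimated correlation, and the neutrophil lists had adjusted p = 0.325 and 0.378. Padi2 fell by 2.27 ± 0.16, and the HSP110 and HSP40 chaperones Hsph1 (-1.22) and Dnaja1 (-0.78), Chordc1 (-0.71) and P4ha1 (-0.64) were lower.

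**Figure D5:**
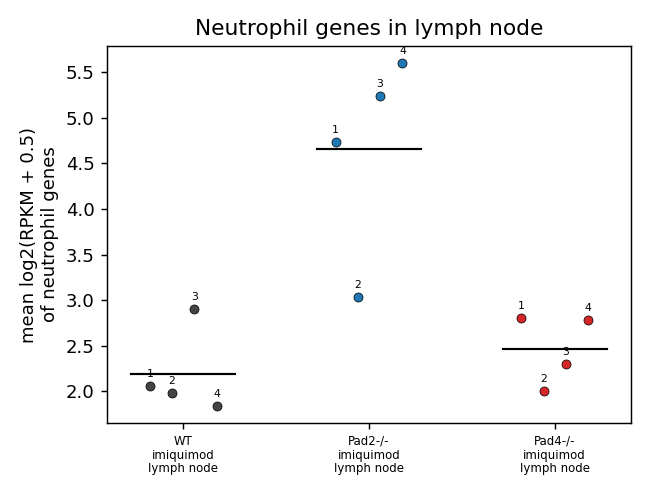
Mean log2(RPKM + 0.5) of the 27 tested neutrophil genes in each lymph node library by genotype under imiquimod; points are libraries, numbers are replicates and short lines group means. Pad2-/- libraries were at 4.73, 3.04, 5.24 and 5.60, and the highest WT library at 2.90.

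In all, 50 genes were higher and 7 lower in Pad2-/- lymph node, with 1459 of 12285 at an unadjusted p under 0.05. The Pad2-/- replicates 3 and 4 stood apart from the other 10 lymph node libraries: the median RPKM of tested genes was 6.84 and 6.23 there and 7.79 or more elsewhere, Slpi was at 9071 and 8168 RPKM against 1102 or less, and Epcam at 21.5 and 32.4. Without both of them the count was 6 genes, and the block of replicates 1 and 2 against 3 and 4 gave 96. Neutrophil genes were highest in these libraries and lowest, among those of Pad2-/-, in replicate 2, without which the count was 230. It was 5 without WT replicate 4, 6 without WT replicate 1 or Pad2-/- replicate 3, 8 without WT replicate 2 or Pad2-/- replicate 4 and 9 without Pad2-/- replicate 1, and a fit of only the 2 groups gave 5. Of the 19 genes named by rule that passed, only Padi2 (1 gene) passed whichever library was left out; Retnlg, S100a8 and S100a9 did not pass in 6 of the 8 such fits. Within 10 Mb of Padi2, 3 of 211 tested genes passed against 53 of 12048 elsewhere (Fisher's exact test, two-sided, p = 0.0717). With Padi2 itself left out, 2 of 210 did (Fisher's exact p = 0.243). The median of all genes shifted by 0.123 log2 with median-ratio scaling and 0.104 with quantile normalization.

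Between the libraries labelled Pad4-/- and WT lymph node, 1 gene passed. Itga2b, the integrin chain of platelets, was higher by 1.30 ± 0.18 (5.23 ± 1.39 against 1.78 ± 0.136 RPKM, n = 4 and 4, limma adjusted p = 0.0454). Cda (1.35, adjusted p = 0.159), Ccl12 (1.0), Ch25h (0.64) and Cxcl14 (-1.39, each adjusted p = 0.174) had the next smallest p-values and did not pass. Erythroid genes were lower as a list (median -1.75, adjusted p = 2.17e-07, with 0 of 12 called over all genes by limma and 7 adjusted over the list alone), as were adipocyte (median -0.91, adjusted p = 3.66e-07) and gland genes (median -0.83, adjusted p = 9.36e-05; 2 over the list alone), markers of blood and of tissue around the node, and mast cell genes were higher (median 0.97, adjusted p = 1.13e-06; 5 over the list alone). Secretory, plasma cell, interferon, TLR, cell cycle, B cell and monocyte lists were lower, and megakaryocyte, handling stress, pan-T, mature neutrophil and progenitor lists higher. Of the 18 lists that passed, the smallest adjusted p with an estimated correlation was 0.162. Without the libraries labelled Pad4-/- 3 and 4 the mitotic and DNA replication lists turned higher (medians 0.28 and 0.23, adjusted p = 0.000876 and 0.000883). The B cell, pan-T, mature neutrophil, progenitor and handling stress lists then did not pass (adjusted p = 0.0657 to 0.206). For these 7 lists the adjusted p with an estimated correlation was 0.665 to 0.672. At an unadjusted p under 0.05 there were 485 genes. When 1 of the WT libraries or of the libraries labelled Pad4-/- 1, 3 and 4 was left out, 0 genes passed, and 2 genes passed without the library labelled Pad4-/- 2. Without the libraries labelled Pad4-/- 3 and 4 the count was 0, as it was with the block of replicates 1 and 2 against 3 and 4. Within 10 Mb of Padi4, 0 of 210 tested genes passed against 1 of 12049 elsewhere (Fisher's exact test, two-sided, p = 1).

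Against the libraries labelled Pad4-/-, Pad2-/- lymph node had 71 genes higher and 41 lower. Retnlg (3.13), Ltf, lactoferrin (3.08), and Camp (3.02) were higher, and Cd209g (-3.45), Cd209f (-3.35) and Cd209b (-2.99 ± 0.48, 16.8 ± 8.09 against 154 ± 121 RPKM, n = 4 and 4, limma adjusted p = 0.0131), lectins of marginal zone and sinus macrophages, were lower. The scavenger receptor Marco (-2.47), Timd4 (-1.66) and Siglec1 (-1.60), of resident macrophages, were lower too and Cd5l higher (1.62); the resident macrophage list did not pass. Of the lymph node libraries, those labelled Pad4-/- 3 and 4 held the highest values: Cd209f was at 72.3 and 38.5 RPKM against 14.3 or less in the other lymph node libraries and Marco at 229 and 149 against 60.4 or less. Padi4 was higher at 2.49 ± 0.43 and Padi2 lower at -1.88 ± 0.16. Neutrophil precursor (8 of 14 higher, all 14 over the list alone; median 2.66, adjusted p = 1.96e-35), mature neutrophil (10 of 13, 11 over the list alone; median 1.51, adjusted p = 2.47e-32) and eosinophil genes (1 of 6, Ccr3 at 1.54, and 3 over the list alone; adjusted p = 3.15e-07) were higher, with adjusted p = 0.0437, 0.0347 and 0.0116 with an estimated correlation. Secretory (median 0.42, adjusted p = 5.2e-15, and 0.286 with an estimated correlation) and plasma cell genes (0.52, adjusted p = 1.18e-09, and 0.286) were higher by direction, and the type I interferon, interferon-gamma response and conventional dendritic cell lists lower (adjusted p = 0.726 with an estimated correlation). Monocyte, erythroid, adipocyte and gland lists were higher too, with adjusted p = 0.286 to 0.798 with an estimated correlation. Without Pad2-/- replicates 3 and 4 the secretory, plasma cell, monocyte, erythroid and conventional dendritic cell lists did not pass (adjusted p = 0.186 to 0.784). Without the libraries labelled Pad4-/- 3 and 4 both interferon lists (adjusted p = 0.932 and 0.481), the conventional dendritic cell list (adjusted p = 0.0728) and the adipocyte list (adjusted p = 0.0502) did not. The mature neutrophil and precursor lists passed without either pair (adjusted p = 3e-12 and 4.88e-14 without the former, 9.7e-26 and 3.9e-27 without the latter). These p-values were 0.263 for both lists, and 0.1 and 0.105, with an estimated correlation. The count was 9 without Pad2-/- replicates 3 and 4, and also 9 without the libraries labelled Pad4-/- 3 and 4. Without single Pad2-/- libraries it was 29 (replicate 1), 233 (2), 14 (3) and 17 (4), without single libraries labelled Pad4-/- it was 71 (1), 36 (2), 52 (3) and 12 (4), and a fit of only the 2 groups gave 43. Of the 22 genes named by rule, Ccr3, Cd209f and Padi2 passed whichever library was left out. The median of all genes shifted by 0.121 log2 with median-ratio scaling and 0.109 with quantile normalization.

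Both knockouts were compared with the same WT libraries, so that chance values are shared. In imiquimod spleen 10 genes were higher in both and 31 lower in both, against 0.284 and 2.28 for independent lists of these sizes and at most 0 in 20 simulations of unchanged groups, where hardly any gene can pass, so that these do not show what shared libraries add to lists of this length; Cd8a and Ctsw were among those higher in both. Across genes the fold changes correlated at r = 0.31 (0.497 in simulated unchanged groups), with a covariance of 0.0193 against 0.0302. In every simulation here the noise was independent between genes. Leaving out 1 library moved r in imiquimod spleen from 0.052 to 0.522, across the simulated value, so that it is not read as lying below that value. In control spleen r was 0.167 (simulated 0.499) with a covariance of 0.00502 against 0.00609, and 1 gene, Ahsa1, was lower in both, against 0.00401 for independent lists. With 3 WT libraries per group the WT group of spleen could not be parted with at least 2 libraries on each side, and part of the overlap may come from the shared controls. In lymph node r was 0.37 (simulated 0.5) with a covariance of 0.024 against 0.0209, and between 0.0717 and 0.277 when each knockout was set against separate pairs of WT libraries. The simulation gave every group the same spread per gene, while the median SD was 0.14 in WT, 0.25 in Pad2-/- and 0.216 in the libraries labelled Pad4-/-. It therefore on the whole overstates what shared WT libraries add in lymph node, and an r below 0.5 shows no lack of a shared effect there. Genes are not independent replicates, and no p is given for these values.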

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

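The tests of a strain segment (with both fits), of shared reads, of libraries 3 and 4, of blood, of WT RNA, of the deleted part and of carried-over RNA were chosen only after the results were seen; the test of the scaling of the libraries and the interaction tests were not.

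In control spleen, genes that differed from WT were gathered beside the targeted locus: of the other genes past the threshold in Pad2-/-, 13 lay within 10 Mb of Padi2, all starting between 144892534 and 149585111, against 3 elsewhere (Fisher's exact test with Padi2 left out, two-sided, p = 3.58e-21), and in Pad4-/- 6 lay within 10 Mb of Padi4 against 11 elsewhere (p = 2.3e-07). These counts depend on the fit, and with only the control groups in it they were 16 against 26 (Fisher's exact p = 3.01e-18) and 43 against 1277 (p = 2.06e-05), so that most genes that passed in Pad4-/- lay elsewhere. Reads shared between zinc finger paralogs cannot account for all of them, since their share was 0.308 near Padi2 and 0 near Padi4. The 13 genes near Padi2 had the same sign in imiquimod spleen, as did all 11 tested in lymph node, and 5 of 6 and 6 of 6 near Padi4. Fewer of them passed the threshold there: 7 and 2 near Padi2, and 4 and 0 near Padi4. Fisher's exact test, here and above, takes neighbouring genes as independent, which they need not be. Snora16a and Snora44, for instance, start at 132309465 and 132309953. Its p-values may therefore overstate how far such genes gather near the loci. In the fit of all spleen groups, the 13 genes all lay at higher positions than Padi2, the nearest 3.99 Mb away. The 6 genes near Padi4 all lay at lower positions than Padi4. A segment of another strain carried along with each targeted allele is a candidate explanation, raised by these same values and so not tested by them. An effect of the lost enzyme on its neighbours was not tested either and stays open.

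In lymph node, neutrophil genes were higher in Pad2-/- than in WT, with mean log2(RPKM + 0.5) levels of the 27 genes of 4.73, 3.04, 5.24 and 5.60 against 2.06, 1.98, 2.90 and 1.84. Blood left in the node would raise erythroid genes as well, whose median was -1.01, and scaling of the libraries was excluded by a median of 1.92 for the mature neutrophil genes after quantile normalization. Replicates 3 and 4 stand apart in other genes too, and without them the count of genes fell from 57 to 6, while the mature neutrophil list stayed higher (median 1.36, adjusted p = 1.88e-15, and 0.325 with an estimated correlation). The count fell to 6 without WT replicate 1 as well, so that this fall is not particular to them. Pad2-/- replicate 1 (4.73) also lay above every WT library, so that replicates 3 and 4 alone do not carry the difference. Replicate 2 (3.04) lay only 0.14 above the highest WT library (replicate 3, 2.90). A difference carried by some of the Pad2-/- libraries therefore cannot be told apart from one of the genotype. A larger number of neutrophils in Pad2-/- lymph node may lie behind the values, as a hypothesis that needs cell counts.

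Padi4 was at 0.607 and 1.2 RPKM in the libraries labelled Pad4-/- 3 and 4 of lymph node, against 0.0958 and 0.131 in replicates 1 and 2. RNA of a WT node in place of the labelled one is argued against by 11 other genes of chromosome 4 that mark Pad4-/- spleen: the lower of libraries 3 and 4 had 0.868 of the shift of replicates 1 and 2, where the WT libraries held -6.23% to 11.9% of it, although the Pad2-/- libraries, at -13.5% to 59.4%, show that these genes are not particular to Pad4-/-. A part of the transcript outside the deletion would show in spleen as well, where Padi4 in Pad4-/- was at most 0.0781 of WT. RNA carried over from an imiquimod spleen is argued against too, since S100a8 (159 and 180 RPKM against a WT mean of 139), Ngp (21.7 and 35.8 against 24.8) and the other 3 most abundant neutrophil genes lay above the lowest level in WT and the libraries labelled Pad4-/- 1 and 2 by a median of at most 0.274 of the addition that Padi4 predicts. For a Pad2-/- node as the source this median reached 0.504 in library 4 and 0.393 in library 3 (both from replicate 1), so that this source stays open, and no biological explanation was tested.

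Among 114 groups of 4 lymph node libraries examined for 38 genes, 6 had 1 library far from the other 3. Chance gives about 1 in 20, which is about as many, so that by their number these 6 cannot be told from chance. In Pad2-/- replicate 2, Retnlg was at 75.0 RPKM against 439 to 617, Mmp9 at 8.19 against 33.0 to 40.4 and Ccl12 at 6.83 against 5.30 to 5.52. Padi2 was at 5.11 RPKM in the library labelled Pad4-/- 2 against 3.65 to 3.8, Cebpe at 0.938 in WT replicate 3 against 0.458 to 0.510 and Olfm4 at 1.11 in the library labelled Pad4-/- 1 against 0.476 to 0.559. The effect of imiquimod on spleen differed from WT by the interaction test for 4 genes in Pad2-/-, Angptl7 (1.91), Zfp990 (-1.61), Zfp534 (-1.85) and Cenps (-1.34). It differed for 8 genes in Pad4-/-, Cd8b1 (1.91), Cd8a (1.60), Gzmm (1.42), Klrd1 (1.06), Ctsw (1.05), Samd3 (0.91), Padi4 (-2.91) and Rn4.5s (-2.70).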

How the results depend on the processing

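Array weights gene by gene, the test of genes near the targeted loci without the targeted gene (also with only the control groups and with array weights gene by gene), the fits without 2 libraries of a lymph node group and median-ratio scaling in the list tests were added after seeing the data; the other alternatives were planned. Among named genes past the threshold, 2894 of 3240 values with 1 library left out and 4410 of 4741 under the other alternatives stayed past it in the same direction, the rest (346 and 331) missed it in the same direction and 0 reversed. Most of these genes were named for imiquimod against control (136 in WT, 129 in Pad2-/- and 128 in Pad4-/-), where 0 were lost with 1 library left out. All 346 losses thus fell in the comparisons between genotypes and the interactions. For Pad2-/- against WT lymph node, 18 of 19 named genes were lost in at least 1 such fit. Genes that did not pass reversed in 5 cases: Padi4 under imiquimod in Pad4-/- spleen (0.05) was at -0.36 with quantile normalization, -0.019 with array weights, -0.025 with array weights gene by gene and -0.066 without Pad4-/- imiquimod replicate 1 (its lowest with 1 library left out, the highest being 0.141), and its Pad2-/- interaction (-0.46) was at 0.034 with array weights. Genes that did not pass did so in the same direction in 21 other cases (2 with 1 library left out, 19 under the other alternatives). They were Padi2 in Pad4-/- against WT under imiquimod with median-ratio scaling and quantile normalization (0.25 and 0.26) and in controls with only the groups compared (-0.20), and Padi4 in Pad2-/- against WT lymph node without Pad2-/- replicate 2 (2.40). In the libraries labelled Pad4-/- against WT they were Cda (1.44 with quantile normalization and 1.55 without the library labelled Pad4-/- 2) and Cxcl14 (-1.39 with only the groups compared). The other 14 passed with array weights of either kind. The cause of these and of the following changes was not tested, except that fits of fewer libraries or only 2 groups have fewer degrees of freedom, and a fit with no filter tests more genes. A fit of only 2 groups also has its own spread. In the fit of all spleen groups the median standard error was 0.121 for each comparison of 2 groups. Median SDs were 0.0649 to 0.0766 in control and 0.167 to 0.177 in imiquimod spleens. That shared error is on the whole too small under imiquimod and too large in controls.

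With an estimated correlation in place of the preset one, 0 lists passed in each of the 8 spleen comparisons of groups, in the Pad2-/- interaction and in the libraries labelled Pad4-/- against WT in lymph node; 1 passed in the Pad4-/- interaction and 3 in each of the other lymph node comparisons. With median-ratio scaling 9 lists passed in Pad4-/- against WT controls (main 14) and 8 in the Pad4-/- interaction (main 13), where quantile normalization gave 7.

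The numbers of genes past the threshold changed by more than 1.5 times as follows. Pad2-/- against WT under imiquimod in spleen (58) gave 30 with median-ratio scaling, 2 with only the groups compared, 2751 with array weights and 1015 gene by gene. Pad4-/- against WT under imiquimod (871) gave 4 with only the groups compared. In controls Pad2-/- (17) gave 43, 99 and 82, and Pad4-/- (18) 1324, 1758 and 1677, with only the groups compared, array weights, and array weights gene by gene. Pad2-/- against Pad4-/- in spleen (40) gave 82 with quantile normalization, 3 with only the groups compared, and 6192 and 3601 with the 2 kinds of array weights. The Pad2-/- interaction (4) gave 2 with a pseudocount of 0.1, 1 with only the groups compared, 1737 and 412 with array weights, and the Pad4-/- interaction (8) 665 and 366. In spleen the iteration behind the array weights did not converge and gave Pad2-/- imiquimod replicate 3 a weight of 59. In lymph node, Pad2-/- against WT (57) gave 15 with no filter, 5 with only the groups compared, 26 with array weights gene by gene, and 6 without Pad2-/- libraries 3 and 4. The libraries labelled Pad4-/- against WT (1) gave 0 with no filter, 0 with median-ratio scaling, 6 with only the groups compared, 11 and 10 with array weights, and 0 without the libraries labelled Pad4-/- 3 and 4. Pad2-/- against the libraries labelled Pad4-/- (112) gave 19, 43, 22 and 13 with no filter, only the groups compared and the 2 kinds of array weights, and 9 without Pad2-/- libraries 3 and 4 or without the libraries labelled Pad4-/- 3 and 4. The correlation of both knockout effects in control spleen (0.167) was 0.27 with no filter.

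Leaving out 1 library gave 8184 to 8647 genes for imiquimod in WT, 8078 to 8848 in Pad2-/- and 7604 to 8203 in Pad4-/-. It gave 12 to 739 for Pad2-/- and 139 to 1507 for Pad4-/- against WT under imiquimod, 10 to 13 and 7 to 11 in controls, 18 to 1751 for Pad2-/- against Pad4-/-, and 3 to 7 and 4 to 756 for the interactions. In lymph node it gave 5 to 230, 0 to 2 and 12 to 233. Lists past the test numbered 14 to 19, 15 to 18 and 19 to 21 for imiquimod, 10 to 17 and 8 to 15 for the knockouts under imiquimod, 4 to 11 and 11 to 18 in controls, 11 to 17 for Pad2-/- against Pad4-/-, 7 to 14 and 11 to 18 for the interactions, and 9 to 15, 16 to 22 and 10 to 17 in lymph node. The correlation of both knockout effects was 0.052 to 0.522, 0.0746 to 0.287 and 0.307 to 0.448 in imiquimod spleen, control spleen and lymph node. The libraries that decide each count are named with the results.

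Replicate numbers were not taken to pair the libraries, since not every same-numbered pair correlated above 0.1, a rule that a real pairing could fail too. Same-numbered pairs correlated above 0.1 in 14 of 45 pairs in spleen and 5 of 12 in lymph node. A library correlated best with its own number in 42 of 90 and 7 of 24 cases, where chance gives 30 and 6. The median correlation in spleen was 0.0544 for the same number and -0.0136 for others, so that a pairing there is not excluded. The replicate block gave 32 genes for Pad2-/- against WT under imiquimod in spleen and 0 for the libraries labelled Pad4-/- against WT in lymph node, and stayed within 1.5 times elsewhere. The block of replicates 1 and 2 against 3 and 4 gave 96 genes for Pad2-/- and 0 for the libraries labelled Pad4-/- against WT. The absolute depth is unknown, so what it limits was not tested.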

Other observations

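The test of T cells of every kind was chosen only after the results were seen; the splits of the libraries were planned.

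Markers of tissues around or inside the lymph node varied from library to library. Adipoq, the adipocyte hormone, ranged from 1.53 to 43.6 RPKM, Krt8, of simple epithelia, from 0.296 to 9.30, and Csn2, a milk casein, was at 20.2 and 21.6 in Pad2-/- replicates 1 and 2 against 0.0967 to 10.6 in the others. Slpi was at 9071 and 8168 RPKM in Pad2-/- replicates 3 and 4 against 356 to 1102 in the other lymph node libraries, and Epcam, an epithelial adhesion molecule, at 21.5 and 32.4 against 6.78 to 10.1. The same libraries lay at 37.8 and 52.0 on the first principal component (39.2% of the variance), against -18.3 to -0.27 for the others. In the libraries labelled Pad4-/- 3 and 4, Cd209f was at 72.3 and 38.5 against 1.05 to 14.3 and Marco at 229 and 149 against 10.7 to 60.4.

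In spleen the first principal component held 83.6% of the variance and parted imiquimod from control libraries. Hbb-b1 ranged from 945 to 26640 RPKM among imiquimod spleens, within every genotype by more than its range in controls.

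Cd8a was at 3.59, 6.0 and 5.51 RPKM in WT imiquimod spleens, 9.60, 10.2 and 11.1 in Pad2-/- and 19.1, 18.2 and 19.01 in Pad4-/-. A larger share of T cells of every kind in Pad4-/- would raise the other pan-T cell genes as much, but their median difference from WT was 0.40 over 18 genes against a mean of 1.94 for Cd8a and Cd8b1, a ratio of 0.207. Cd8a and Cd8b1 were set apart as the largest rises of the list, which made a ratio under 1 likely beforehand. The other 18 genes ranged from -0.0641 to 0.901, so that a smaller rise of T cells of every kind is not excluded. A smaller loss of CD8 T cells in Pad4-/- than in WT spleen may fit these values, as a hypothesis that needs cell counts.

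Other splits of the same libraries were run for each count of genes. In lymph node, 1 of 35 splits (the real one) gave as many genes for Pad2-/- against WT (57, highest other 8), the smallest share these libraries allow. That share is under 0.05, without adjustment over the comparisons. This does not part the genotype from Pad2-/- replicates 3 and 4: the count was 6 without both, 5 in a fit of only the 2 groups and 5 to 230 with 1 library left out. By the share chance cannot be excluded for the libraries labelled Pad4-/- against WT (1, highest other 3; 2 of 35) or for Pad2-/- against them (112, highest other 917; 2 of 35). For the interactions 100 of 200 possible splits were drawn. The share was 3 of 100 for Pad4-/- (8, highest other 258), under 0.05, and 6 of 100 for Pad2-/- (4, highest other 94). Other splits gave far more genes than the real one in both, and a single library moves the Pad4-/- count from 8 to 756. Padi4 itself is among those 8 genes. Chance is therefore not excluded by the share for either interaction. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Their real and highest other counts were 8807 and 0 (WT), 8743 and 32 (Pad2-/-) and 8387 and 0 (Pad4-/-) for imiquimod, with 1 split as large in each. For the knockouts against WT they were 17 and 0 (Pad2-/-) and 18 and 0 (Pad4-/-) in controls, with 1 split as large in each, and 58 and 1289 (Pad2-/-, 3 splits as large) and 871 and 1232 (Pad4-/-, 2) under imiquimod. For Pad2-/- against Pad4-/- they were 40 and 4009 (2). The splits, those for the interactions included, that gave several times the real count point to a structure among the libraries that the genotypes do not hold.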
